A study of Rattus norvegicus with 8 samples.

How the data were processed

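Gene expression was measured on Affymetrix oligonucleotide arrays in placentas of Sprague-Dawley rats on gestational day 18.5. There were 8 arrays, 4 from dams on a control diet and 4 from dams on an iron-restricted diet, and each array carried RNA pooled from 2 placentas of a single dam. The dam was therefore the replicate, and the spread between arrays of a group includes biological variation between dams. The sex of the pooled fetuses is not given in the labels. Frozen tissue was homogenised in TRIzol, and the RNA was cleaned on a column with DNase digestion and labelled with biotin after sense-strand cDNA synthesis, per the labels' protocols.

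The deposited table holds log2 expression values made by the authors with the robust multi-array average (RMA) method at the gene level in Affymetrix Expression Console, per the series' design text. RMA corrects the background, forces the same distribution of probe values on every array and summarises the probes of a transcript cluster. It leaves relative differences between arrays and no absolute amounts, and an overall shift of all transcripts would be removed by it. The submitters' processing notes also name Transcriptome Analysis Console, and versions and genome build are not given in the sources used here. The values are rounded to 2 decimals, and about 1% of the features of each array lie above 16, which is more than the log2 value of a 16-bit scanner can reach. The log2 scale may therefore be stretched, and every fold in the text is a fold on the deposited scale. Scanner files and detection p-values were not used here, so no transcript could be called absent.

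The table has 23188 features. The platform annotation pairs 15049 of them (64.9%) with 1 gene symbol, 0 with several and 8139 with none. All 15049 symbols were found by Entrez identifier in the RefSeq gene table and 0 of them changed. Where a gene had more than 1 feature (10 genes), the feature with the highest mean over the 8 arrays was used, which left 15037 genes. The unnamed features were tested and counted apart. No genome of the build used by the authors was given, so no coordinates are printed.

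The diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, with no filter and no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are the iron-deficient mean minus the control mean on the log2 scale, with the standard error (SE) of the limma fit. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists with at least 5 measured members. The test was repeated with an estimated correlation and with fry. The 31 lists name 851 entries, of which 723 were measured, and cover iron handling, heme synthesis, iron-sulfur cluster assembly, oxidative phosphorylation, hypoxia-inducible factor targets, erythroid cells, the trophoblast types, placental hormones and proteases, transport, steroid and cholesterol synthesis, stress and immune responses, proliferation, imprinted genes and markers of other tissues such as decidua and yolk sac. Of the 2 lists too short to test, the Y-linked list had 2 measured members and *Xist* was not among the named features. Members were matched by current symbol, and some genes stand in more than 1 list.

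The design, the alternatives, the gene lists and the naming rule were fixed before the data were examined. The rule named up to 12 genes per direction with the largest change among those past the threshold with non-overlapping groups. Where fewer than 10 passed, it filled up to 10 with the smallest unadjusted p among genes that changed at least 1.5-fold with non-overlapping groups. It also named 4 members of each list with the smallest p, and 8 iron and hypoxia genes always. Placeholder symbols (22 genes) were not named by its first part. Single values per array, such as list means, were compared with two-sided exact permutation tests over the 70 arrangements of the 8 arrays, for which the smallest possible p is 0.02857.

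The fit was tested on simulated data for the comparison of the iron-deficient with the control diet, with 15037 genes, 200 of them changed, in 20 runs. It recovered 20.7% of the genes changed 1.5-fold, 87.8% of those changed 2-fold and 100% of those changed 4-fold or 16-fold, and 5.28% of its calls were false. The simulated noise was independent between genes, and with so many changed genes the adjusted threshold is easier to pass. These rates therefore do not carry over to data with few changed genes. In the real data *Hbz* at 5.512-fold (limma adjusted p 0.4249) and *Sorbs2* at 2.558-fold (0.2568) did not pass. In 100 simulated runs with a list of 25 unshifted members correlated at 0.4, camera gave a p below 0.05 in 61 runs with the preset correlation and in 10 runs with an estimated one. Calls made with the preset correlation on lists whose members move together between arrays are therefore more frequent than the nominal rate.

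Alternatives were another quantile normalization, median centring, the dimmest 25% or 50% of genes left out, all features, the mean of a gene's features, other variance models and array weights, the dam number as a block, Y-linked, erythroid and decidual means as covariates, other list tests, other thresholds, and each dam left out in turn. After the data were seen, the yolk sac list mean as a covariate and the omission of both arrays with low Y-linked signal were added. No arrays were left out of the main comparison. Between 0.94% and 1.3% of features had the same value to 2 decimals in any pair of arrays, so no array was a copy of another. The number of arrays limits the precision. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.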

Results

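The arrays measured transcript levels in whole rat placenta on gestational day 18.5, to find how maternal iron deficiency alters placental gene expression. Control dams ate a diet with 37 mg/kg iron from 2 weeks before mating. Iron-deficient dams ate 3 mg/kg iron for the 2 weeks before mating and 10 mg/kg during pregnancy. There were 4 dams per diet. Every array had a median log2 value between 6.67 and 6.705 over its 23188 features. Pearson correlations between arrays, across genes, averaged 0.9916 within a diet and 0.9909 between diets, so the arrays of a diet were hardly more alike than arrays of different diets. The first principal component held 22.2% of the variance and the second 17.9%. Scores on the first ran from -24.74 to -2.67 on control arrays and from -3.42 to 31.21 on iron-deficient arrays. Only control dam 4 (-2.67) and iron-deficient dam 1 (-3.42) crossed, so this component nearly separated the diets, which was not tested. Its ends were also the arrays with the widest and the narrowest spread over all features. These were control dam 3 (SD 3.286) and iron-deficient dam 4 (SD 3.171), so diet and array spread cannot be told apart on this component. The Y-linked genes *Ddx3y* and *Eif2s3y* were low on control dam 4 (4.77 and 5.06) and on iron-deficient dam 1 (5.27 and 5.92), and lay between 9.42 and 11.67 on the other 6 arrays.

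The clearest difference between the diets was in *Alox15*, which encodes a 12/15-lipoxygenase that oxygenates polyunsaturated fatty acids. Its log2 value rose from 6.17 ± 0.78 (SD, n = 4) in control placentas to 10.57 ± 1.26 (SD, n = 4) under iron deficiency. The difference was 4.39 (SE 0.54), or 21.0-fold on the deposited scale, with a limma adjusted p of 0.04549. The 4 control arrays lay between 5.13 and 6.89 and the 4 iron-deficient arrays between 9.36 and 11.91. *Alox15* was the only one of 15037 genes past the threshold (1 higher, 0 lower). At an unadjusted limma p below 0.05 there were 1161 genes, 569 higher and 592 lower, which is 7.72% of genes where chance gives 5%. Values of the diets did not overlap for 601 genes (4%), where chance gives 2.86%. Both chance values are averages, from which genes that vary together can depart, and neither excess was tested. The difference in *Alox15* stayed between 3.94 and 4.79 with any 1 dam left out, but the adjusted p exceeded 0.05 in 6 of these 8 fits, those without each of the 4 control dams (adjusted p between 0.08837 and 0.263) and those without iron-deficient dam 1 (0.1995) or dam 2 (0.1081). Among all 23188 features its adjusted p was 0.06137 and 0 features passed, with 1759 at an unadjusted p below 0.05, and over 22 alternatives its adjusted p ranged from 0.0005709 to 0.3908 and missed the threshold in 13.

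**Figure D1:**
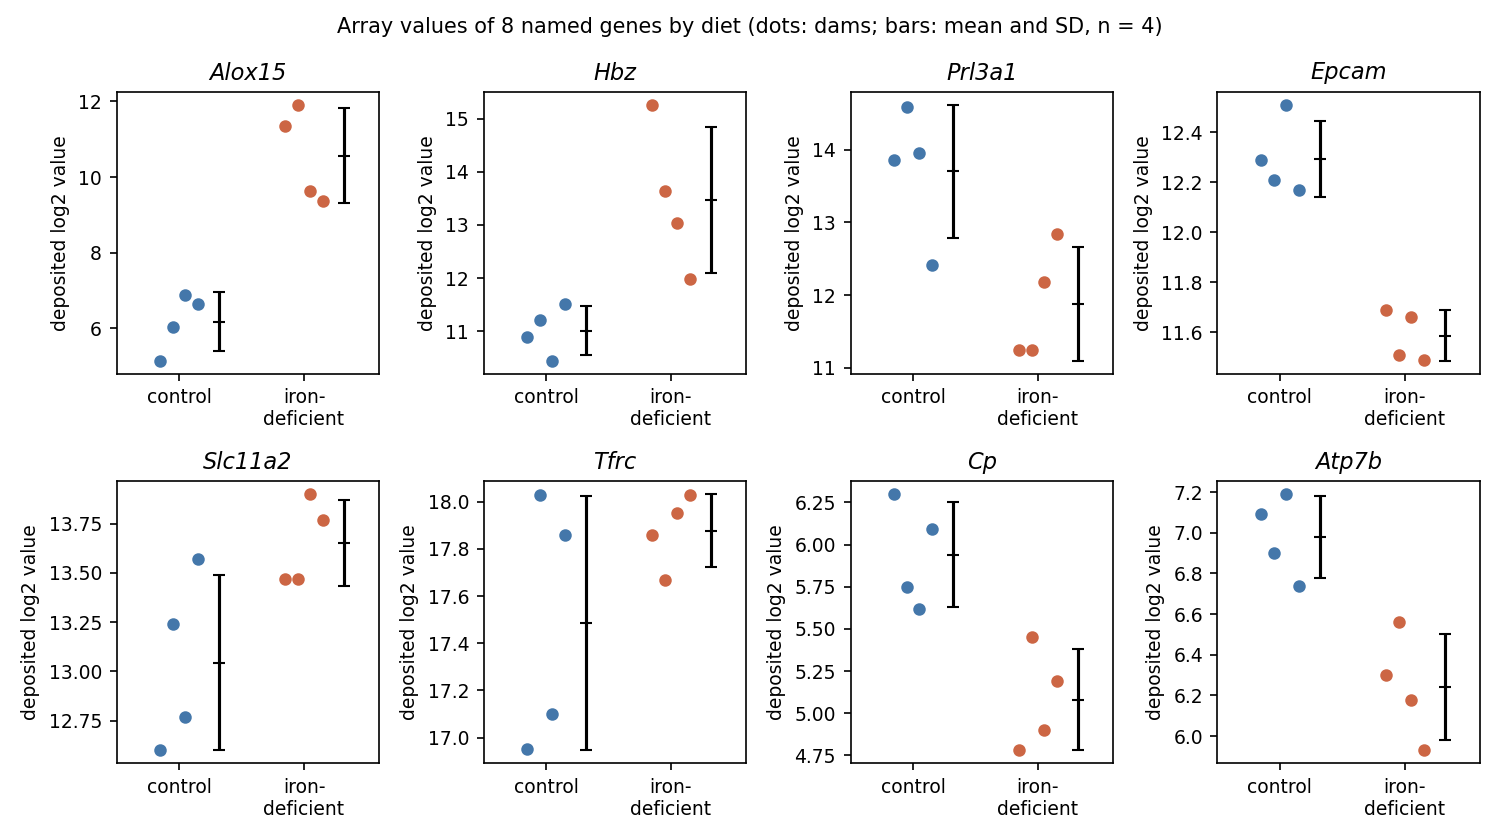
Log2 values of 8 named genes on each array (dots, vertical axis) for the control and the iron-deficient diet, with the mean and SD (black bars, n = 4 dams). *Alox15* was between 5.13 and 6.89 in control placentas and between 9.36 and 11.91 under iron deficiency. The other 7 genes did not pass the test over all genes.

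The genes that came next by the naming rule had non-overlapping diets and at least a 1.5-fold difference but did not pass the test (limma adjusted p between 0.2568 and 0.4482). On the higher side these were *Hbz*, the embryonic zeta globin, with a log2 difference of 2.46 (SE 0.53), *Tnnc1*, the slow skeletal and cardiac troponin C (0.89, SE 0.16), *Abtb1* (0.92, SE 0.17), *Med29*, a Mediator subunit (0.78, SE 0.16), *Nckap5l* (0.64, SE 0.14) and the carboxylesterase *Ces1a* (0.69, SE 0.16). The olfactory receptor genes *Or5p1*, *Or4f15* and *Or7g23b* differed by 0.95, 0.80 and 0.83, from control means of 3.64, 3.15 and 3.38 that lay near the bottom of the scale. On the lower side the first was *Sorbs2*, a cytoskeletal adaptor, at 8.20 ± 0.35 in control and 6.84 ± 0.33 in iron-deficient placentas (difference -1.36, SE 0.21). It was followed by the kinase *Mark4* (-0.84), the calpain *Capn8* (-1.01), *Serpinb5*, which encodes maspin (-0.76), the chemokine *Cxcl13* (-0.79), the pantetheinase *Vnn1* (-0.80), *Mcc* (-0.84), *Dmkn* (-0.90) and the MAP kinase phosphatase *Dusp8* (-0.83). *Epcam*, an epithelial adhesion molecule, was 12.30 ± 0.15 in control and 11.59 ± 0.10 in iron-deficient placentas (difference -0.71, SE 0.14).

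Genes of iron uptake, storage and export differed by less than 1 on the log2 scale, and none of them passed over all genes. *Slc11a2*, the divalent metal transporter DMT1, was 13.05 ± 0.44 in control and 13.65 ± 0.22 in iron-deficient placentas (difference 0.61, SE 0.21), and the transferrin receptor *Tfrc* was 17.49 ± 0.54 and 17.88 ± 0.15 (0.39, SE 0.23). The ferritin chains *Fth1* and *Ftl1* differed by -0.02 (SE 0.16) and -0.08 (SE 0.14), the exporter *Slc40a1* by -0.17 (SE 0.15) and heme oxygenase *Hmox1* by -0.17. The ferroxidase *Cp* was 5.94 ± 0.31 in control and 5.08 ± 0.30 in iron-deficient placentas (difference -0.86, SE 0.20), and the related ferroxidase *Heph* and the ferrireductase *Steap3* differed by -0.58 and -0.48. Of the 33 measured iron-handling genes, 11 were higher and 22 lower, 0 passed over all genes, and 1, *Cp*, passed when adjusted over the list alone (limma adjusted p 0.02977). The list as a group did not pass (mean difference -0.07, camera adjusted p 0.387).

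Pathways that use iron showed no shift past the test. Heme synthesis genes differed by a mean of -0.01 (14 genes, camera adjusted p 0.9082), with *Alas2*, the erythroid first enzyme, at -0.16 (SE 0.37), *Tmem14c* at 0.29, *Slc25a39* at -0.31, *Fech* at -0.36 and *Ppox* at -0.19. The list's median was 0.02, and its mean, median and test differed in sign. The mean was 0.0179 after another quantile normalization. Iron-sulfur cluster assembly genes differed by 0.02 (24 genes, adjusted p 0.8405), with *Bola1* at -0.47, *Iba57* at 0.39, *Nfu1* at 0.27 and *Fdx1* at 0.24. Oxidative phosphorylation genes differed by 0.01 (48 genes, adjusted p 0.9082), with the complex I subunits *Ndufb8* at 0.55, *Ndufs1* at -0.29, *Ndufa4* at -0.33 and *Ndufa5* at -0.31. Targets of hypoxia-inducible factors also had a mean difference of 0.01 (44 genes, 25 higher and 19 lower, adjusted p 0.8751). Among them the angiogenic factor *Vegfa* differed by -0.33 (SE 0.15), the glycolytic enzyme *Pfkp* by -0.41, the lactate exporter *Slc16a3* by 0.41 and *Narf* by -0.38. In these 4 lists 0 members passed over all genes or when adjusted over the list alone.

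Erythroid genes lay on both sides of 0. Of the 31 measured members 12 were higher and 19 lower. At an unadjusted limma p below 0.05, 6 members were higher and 5 lower. Over all genes 0 passed, and 4 passed when adjusted over the list alone, each of them higher under iron deficiency. These were *Hbz* (11.02 ± 0.46 in control, 13.48 ± 1.37 in iron-deficient placentas, list adjusted p 0.01619), the embryonic beta-like globin *Hbe1* (17.30 ± 0.50 and 18.22 ± 0.50, 0.04641), the transcription factor *Gfi1b* (5.44 ± 0.22 and 6.45 ± 0.61, 0.03356) and *Trim10*, a gene of erythroid cells (4.36 ± 0.61 and 5.26 ± 0.04, 0.03794). As a group the list had a mean difference of 0.01 and a median of -0.10 (camera adjusted p 0.9082, direction down), so that mean and median differed in sign. With fry's test for change in either direction its adjusted p was 0.05054.

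Among the globin genes, split after their values were seen, the embryonic ones were higher under iron deficiency, and the adult ones were lower without passing an exact test. The mean of the 4 measured embryonic globins was 11.29 ± 0.37 (SD, n = 4) in control and 12.42 ± 0.69 (SD, n = 4) in iron-deficient placentas. *Hbg1* and *Hbe2* differed by 0.79 (SE 0.26) and 0.31 (SE 0.24). *Hbz* differed most (2.46, SE 0.53), with values from 15.26 on iron-deficient dam 1 to 11.98 on dam 4. It raised the mean difference above the median difference of the 4 genes, which was 0.86. The mean of the 5 measured adult globins was 17.37 ± 0.41 and 16.90 ± 0.38, with *Hba-a3* at -0.83 (SE 0.34), *Hbb-b1* at -0.69, *Hbb-bs* at -0.52, *Hbb* at -0.26 and *Hba-a1* at -0.06. The adult mean differed by -0.47 with a 95% interval of -1.15 to 0.21 and an exact two-sided permutation p of 0.1714, and the embryonic mean by 1.12 with an interval of 0.17 to 2.08. The embryonic mean minus the adult mean of an array was -6.08 ± 0.32 in control and -4.48 ± 0.60 in iron-deficient placentas, a shift of 1.59 with a 95% interval of 0.76 to 2.43. An exact permutation test of this shift gave a two-sided p of 0.02857, the smallest that 4 against 4 arrays can give, but the contrast was formed from the same values, so this p only describes the separation of the arrays and is not independent evidence of it. The adult globins had means above 14 on the deposited scale, where it may be stretched, and transcripts of related globins can share probes.

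**Figure D2:**
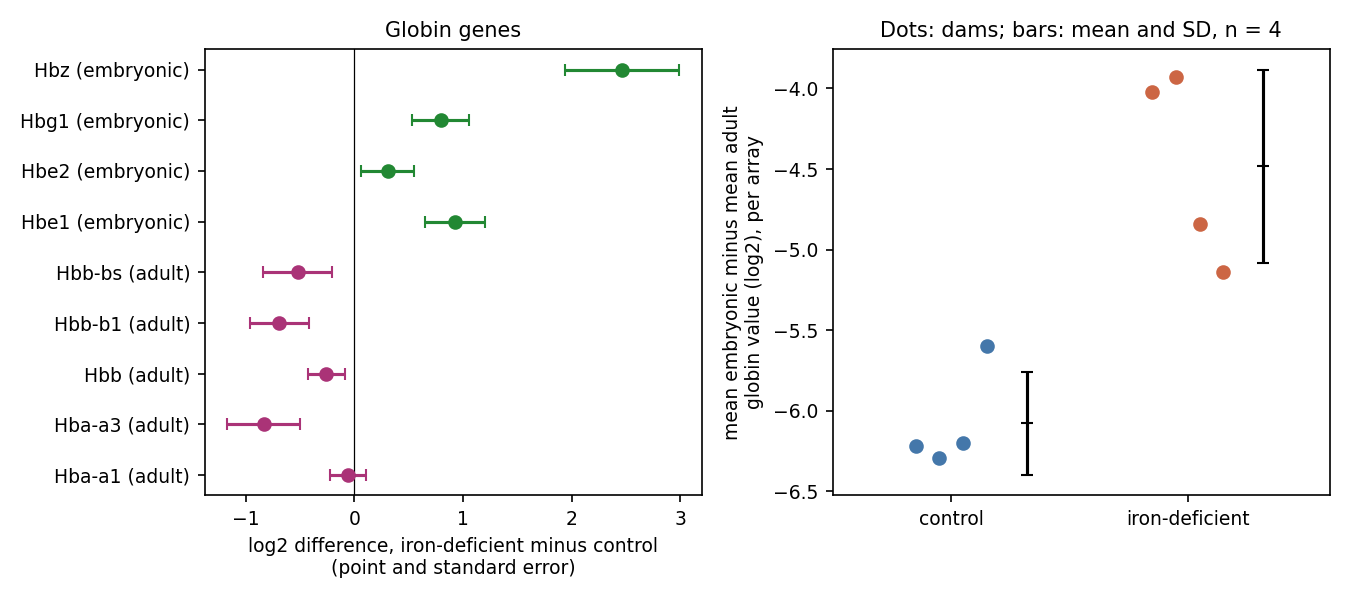
Log2 difference (iron-deficient minus control, horizontal axis) and standard error of the 9 globin genes (left), and the embryonic minus the adult globin mean in log2 units (vertical axis) on each array (right, dots, with the mean and SD of 4 dams as bars). The 4 control arrays lie between -6.29 and -5.6 and the 4 iron-deficient arrays between -5.14 and -3.93.

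None of the trophoblast lists passed as a group in the main comparison, and single members differed. The labyrinth list, whose cells carry the exchange between mother and fetus, had a mean difference of -0.02 and a median of 0.03 (20 genes, camera adjusted p 0.8405), and 1 member, *Epcam*, passed when adjusted over the list alone (0.005484). Its receptor gene *Met* differed by -0.27. Junctional zone genes had a mean of 0.04 and a median of -0.02 (24 genes, adjusted p 0.9305), with *Pcdh12* at 0.55, *Egfr* at -0.31, *Gbe1* at 0.35 and *Ascl2* at 0.28. Giant cell genes were higher by a mean of 0.20 (14 higher and 6 lower of 20) without passing (adjusted p 0.1203). The plasminogen activator *Plau* differed by 0.99 (SE 0.27), the gelatinase *Mmp9* by 1.14 (SE 0.39), *Gata3* by 0.31 and *Cited2* by 0.28. *Mmp9* is also in the neutrophil list, and its value on iron-deficient dam 4 (5.88) lay below the lowest control value (5.92). The giant cell list passed after another quantile normalization (mean 0.23, adjusted p 0.0426), without control dam 3 (0.27, 0.007221) and without iron-deficient dam 4 (0.25, 0.03253). These calls used the preset correlation, and over all 8 arrays its adjusted p was 0.6434 with an estimated correlation, and its mean was 0.13 without iron-deficient dam 2. In the prolactin family of placental hormones, *Prl3a1* was 13.70 ± 0.91 in control and 11.88 ± 0.78 in iron-deficient placentas (difference -1.83, SE 0.44) and was the 1 of 22 members that passed when adjusted over the list alone (0.03027). *Prl5a2* differed by 1.19, *Prl7a4* by -1.01 and *Prl2b1* by 0.27, with *Prl7a4* between -1.54 and -0.53 with 1 dam left out, and the family's mean was -0.10 (adjusted p 0.408). Placental cathepsins and pregnancy-specific glycoproteins differed by -0.03 (16 genes, adjusted p 0.7357), with *Ceacam12* at -0.31, *Ctsj* at 0.42, *Ctsql2* at -0.27 and *Ctsr* at -0.20.

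Nutrient transport genes were lower in 21 of 31 cases, with a mean difference of -0.12 that did not pass (camera adjusted p 0.1203). The copper-transporting ATPase *Atp7b* was 6.98 ± 0.20 in control and 6.24 ± 0.26 in iron-deficient placentas (difference -0.74, SE 0.17) and passed when adjusted over the list alone (0.02959). The amino acid transporter *Slc7a8* differed by 0.47, the fatty acid transporter *Slc27a4* by -0.47 and the fatty acid binding protein *Fabp3* by -0.36. By fry's test for change in either direction this was the 1 list of 29 that passed (adjusted p 0.04374). Camera gave it an adjusted p of 0.01177 without control dam 3 and of 0.03007 without both arrays of low Y-linked signal, with the preset correlation. Over all 8 arrays its adjusted p was 0.8201 with an estimated correlation, and its mean was -0.05 without control dam 2. Imprinted genes differed by -0.03 (21 genes, camera adjusted p 0.7357), with *Igf2r* at -0.50, *Slc22a18* at 0.50, *Zim1* at -0.42 and *Kcnq1* at 0.56. Steroid synthesis genes differed by 0.11 (14 genes, adjusted p 0.387), with *Scarb1* at -0.36, *Tspo* at 0.29, *Cyp11a1*, the side-chain cleavage enzyme, at 0.38 and *Hsd17b3* at 0.39. With 1 dam left out the steroid synthesis mean lay between 0.03 and 0.20.

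Genes of the yolk sac endoderm, an extraembryonic epithelium that makes plasma proteins and lies next to the rodent placenta, were lower under iron deficiency as a group. Of the 25 measured members 24 were lower, by a mean of -0.69, and camera with the preset correlation gave an adjusted p of 2.827e-08, which became an adjusted p of 0.6434 with an estimated correlation. The retinol carrier *Rbp4* was 8.22 ± 0.94 in control and 7.24 ± 0.55 in iron-deficient placentas, *Amn*, an endocytic receptor subunit, differed by -0.56 (SE 0.16), *Hnf4a* by -0.47 and the apolipoprotein *Apom* by -0.99, and 0 members passed over all genes or when adjusted over the list alone. The list mean was 0.81, 0.67, 0.62 and -0.72 on the control arrays and -0.11, 0.12, -0.46 and -0.94 on the iron-deficient arrays, as log2 values centred over the 8 arrays. With 1 dam left out the mean difference lay between -1.05 (without control dam 4) and -0.50 (without iron-deficient dam 4). An exact permutation test of these list means gave a two-sided p of 0.1714, so the list means of the diets did not differ past the threshold.

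**Figure D3:**
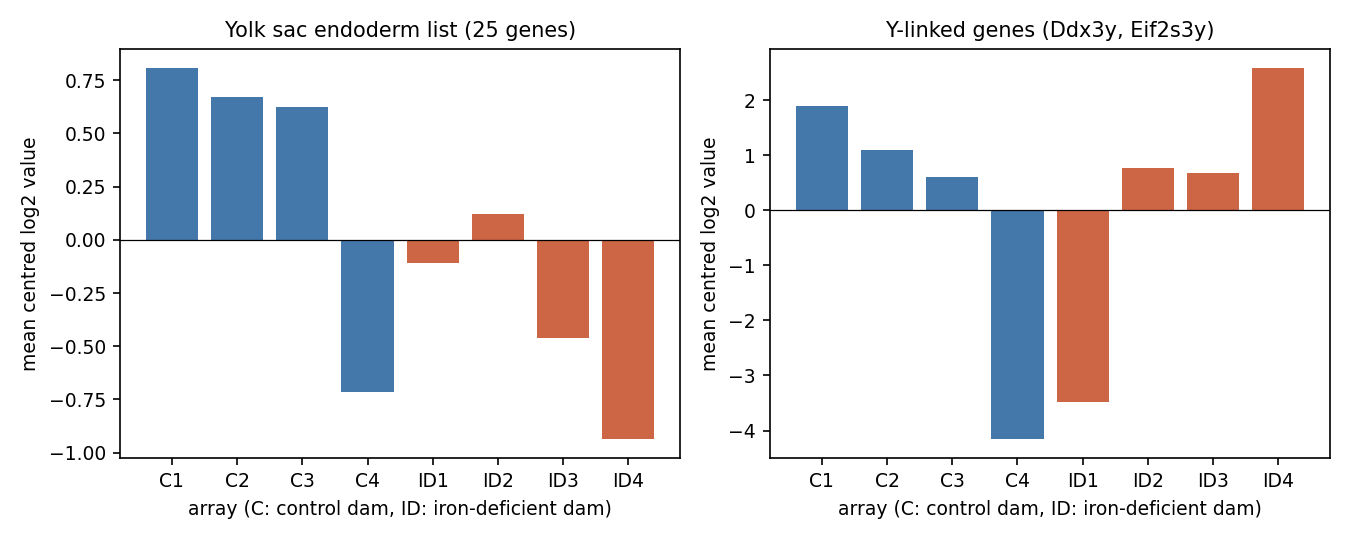
Mean centred log2 value (vertical axes) of the yolk sac endoderm list (25 genes, left) and of the Y-linked genes *Ddx3y* and *Eif2s3y* (right) on each of the 8 arrays, with control dams as C1 to C4 and iron-deficient dams as ID1 to ID4. The yolk sac list mean was between 0.62 and 0.81 on 3 control arrays and -0.72 on control dam 4, and the Y-linked genes were low on control dam 4 and iron-deficient dam 1.

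Stromal matrix genes were also lower as a group. Of 26 measured members 21 were lower, by a mean of -0.19 (camera adjusted p 0.0115, and adjusted p of 0.6434 with an estimated correlation). The matrix protein periostin (*Postn*) differed by -0.58 (SE 0.20), the collagen chains *Col1a1* and *Col1a2* by -0.60 (SE 0.23) and -0.55 (SE 0.22) and *Lum* by -0.49, and 0 members passed over all genes or when adjusted over the list alone. With the yolk sac list mean as a covariate the difference was -0.12 and the adjusted p 0.2895, and the call was also lost without control dam 2 (adjusted p 0.06754), iron-deficient dam 2 (0.06065) or iron-deficient dam 3 (0.1243). Endothelial genes were lower in 17 of 24 cases without passing (mean -0.15, adjusted p 0.06686), with *Emcn* at -0.54, the angiopoietin receptor *Tek* at -0.58, *Tie1* at -0.61 and *Pecam1* at -0.44. The endothelial list passed in 7 alternatives, among them array weights (adjusted p 0.02118), the fits without control dam 3 (mean -0.22, adjusted p 0.002042), control dam 4 (-0.20, 0.01403) or iron-deficient dam 1 (-0.25, 0.0007736) and the fit without both arrays of low Y-linked signal (-0.30, 0.0001369). These calls used the preset correlation, and over all 8 arrays its adjusted p was 0.8201 with an estimated correlation. Its mean was -0.08 without control dam 1, which did not pass. The decidual stroma list, of maternal uterine tissue, differed by -0.05 (23 genes, adjusted p 0.796), with the receptors *Esr1* at -0.50 and *Pgr* at -0.60, *Ramp3* at 0.39 and *Igfbp3* at 0.41. Without iron-deficient dam 3 *Esr1* differed by -0.23 and *Pgr* by -0.26, so that dam carried much of both differences.

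**Figure D4:**
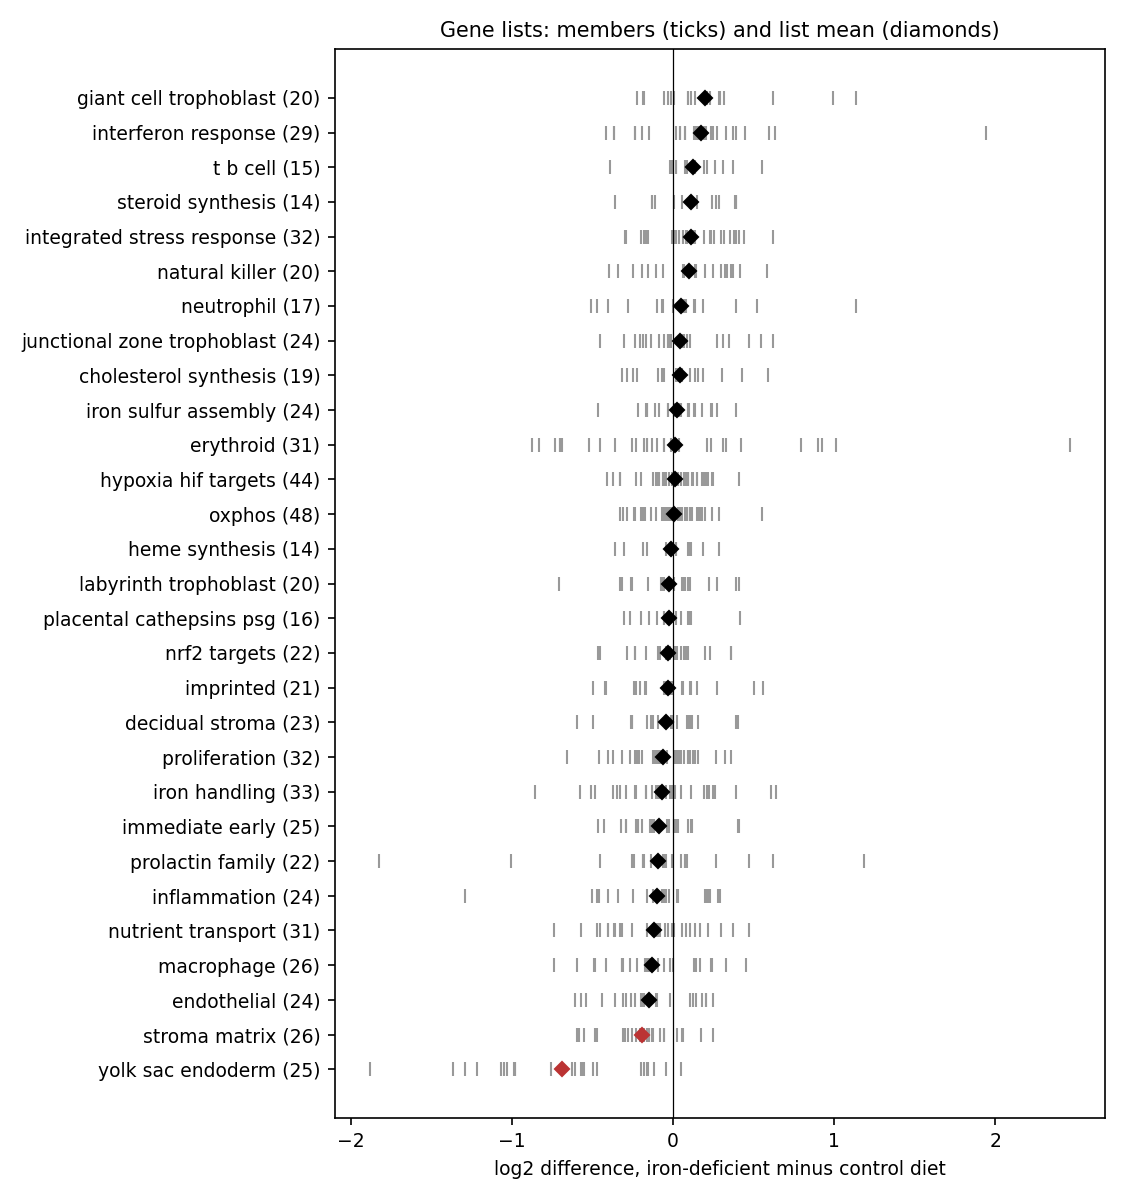
Log2 difference between the diets (horizontal axis, iron-deficient minus control) of the measured members (ticks) and the mean (diamonds) of the 29 tested gene lists, with the number of measured members in brackets. The 2 lists past the threshold of camera with the preset correlation, yolk sac endoderm (mean -0.69) and stromal matrix (-0.19), are in red, and neither passed with an estimated correlation (adjusted p 0.6434 for both).

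Immune cell lists did not pass. Natural killer cell genes differed by a mean of 0.10 (20 genes, camera adjusted p 0.2914), with *Ncr1* at -0.40, *Gzmk* at 0.36, *Gzmc* at 0.58 and *Il2rb* at 0.42. Macrophage genes were lower in 18 of 26 cases (mean -0.13, adjusted p 0.2181), with *Folr2* at -0.60, *Cd163* at -0.49, *Mrc1* at -0.42 and *Adgre1* at 0.45, and they passed without both arrays of low Y-linked signal (mean -0.23, adjusted p 0.03007 with the preset correlation). Over all 8 arrays their adjusted p was 0.6434 with an estimated correlation. Neutrophil genes differed by 0.05 (17 genes, adjusted p 0.6816), with *Mmp9* at 1.14, *Np4* at 0.52, *Ngp* at 0.39 and *Fpr1* at -0.28. T and B cell genes differed by 0.12 (15 genes, adjusted p 0.2914), with *Blk* at -0.40, *Cd3e* at 0.55, *Cd8a* at 0.37 and *Cd247* at 0.31. Interferon response genes were higher in 22 of 29 cases, by a mean of 0.17 that did not pass (adjusted p 0.1203). Among them *Ifit1* was 5.92 ± 1.70 in control and 7.87 ± 0.63 in iron-deficient placentas, *Oas1a* differed by 0.60, *Mx2* by 0.63 and *Gbp2* by -0.42. The interferon list passed with the dimmest 25% of genes left out (adjusted p 0.04076) and without control dam 3 (mean 0.24, adjusted p 0.01177), with the preset correlation. Over all 8 arrays its adjusted p was 0.6434 with an estimated correlation. Inflammation genes differed by -0.10 (24 genes, adjusted p 0.8405), with *Ccl7* at -0.34, *Nos2* at 0.28, *Cxcl2* at -0.41 and *Il1a* at -0.46.

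Genes of the integrated stress response, which *Atf4* directs when translation is restrained, were higher in 24 of 32 cases, by a mean of 0.11 that did not pass (camera adjusted p 0.1037). *Atf4* itself was 14.21 ± 0.17 in control and 14.59 ± 0.11 in iron-deficient placentas, and *Shmt2* differed by 0.41, *Cebpb* by 0.62 and *Trib3* by 0.39. The stress response list passed in 6 alternatives, which were another quantile normalization (adjusted p 0.0426), the dimmest 25% of genes left out (0.0344), array weights (0.03835), the yolk sac mean as a covariate (0.01797) and the fits without control dam 3 (0.007221) or iron-deficient dam 4 (0.02091). These calls used the preset correlation, and over all 8 arrays its adjusted p was 0.6434 with an estimated correlation. Antioxidant targets of Nrf2 differed by -0.03 (22 genes, adjusted p 0.8751), with *Gsr* at -0.47, *Sod1* at 0.36, *Gsta1* at 0.36 and *Nqo1* at -0.46. Cholesterol synthesis genes differed by 0.04 (19 genes, adjusted p 0.7357), with *Insig1* at 0.59, *Stard4* at 0.43, *Mvk* at -0.32 and *Ebp* at 0.31. Proliferation genes differed by -0.07 (32 genes, adjusted p 0.6608), with *Rrm2* at -0.66, *Kif20a* at -0.41, *Ccna2* at -0.46 and *Tk1* at 0.36, and the mean lay between -0.1362 and -0.0045 with 1 dam left out. The immediate early list, which also holds the heat shock gene *Hspb1* (-0.47), differed by -0.09 (25 genes, adjusted p 0.387). *Fosb* differed by -0.43, *Zfp36* by 0.41 and *Egr2* by 0.40. The list mean lay between -0.1335 and -0.0058 with 1 dam left out. With some dam left out, the mean of 19 of the 29 lists fell below 50% of its value over all arrays or changed sign, as did the difference of 18 of the 139 named genes. Over the 29 lists 0 passed with an estimated correlation (smallest adjusted p 0.6434) and 0 by fry's directional test (smallest adjusted p 0.6007), where 7 had an unadjusted p below 0.05 with the preset correlation and 0 with an estimated one.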

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

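The tests of the yolk sac list, and the setting without both arrays of low Y-linked signal, were chosen after the results were seen. A dam was marked where its distance from the nearest of the other 3 dams of its diet as a share of that diet's whole range exceeded Dixon's critical value for 4 samples. Of 336 groups tested 17 (5.1%) were marked, where chance gives about 1 in 20.

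Control dam 4 stood apart for the yolk sac list mean, at -0.72 against 0.62 to 0.81 on the other control arrays (ratio 0.879), for *Rbp4* (6.83 against 8.51 to 8.83, ratio 0.84), *Ctsj* (16.94 against 17.73 to 17.88, 0.84), *Dmkn* (9.36 against 10.05 to 10.16, 0.863) and the heme synthesis list mean (-0.09 against 0.03 to 0.04, 0.931). Control dam 3 stood apart for *Cxcl13* (6.31 against 6.06 to 6.08, 0.92), *Bola1* (6.02 against 6.33 to 6.38, 0.861), the junctional zone list mean (0.27 against -0.14 to -0.07, 0.84) and the prolactin family mean (0.44 against -0.12 to -0.04, 0.865). Control dam 2 stood apart for *Hsd17b3* (7.63 against 8.69 to 8.81, 0.898) and the mean of hypoxia-inducible factor targets (0.09 against -0.05 to -0.03, 0.847). Among iron-deficient dams, dam 3 stood apart for *Or4f15* (4.34 against 3.81 to 3.84, 0.943), *Adgre1* (3.93 against 4.64 to 4.75, 0.866) and *Gsr* (9.98 against 10.27 to 10.32, 0.853). Iron-deficient dam 1 stood apart for *Cd3e* (4.82 against 3.73 to 3.89, 0.853) and *Pecam1* (11.62 against 10.89 to 10.97, 0.89), and dam 4 for *Amn* (5.29 against 5.6 to 5.65, 0.861).

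The yolk sac pattern may come from different amounts of yolk sac tissue carried along at dissection. Within the diets, the members varied together from array to array, with a median pairwise correlation of 0.56, where the highest of 1000 random lists matched on brightness had 0.147. Its brightest members were *Afp* (control mean 14.90, difference -1.22), *Apoa4* (12.01, -0.61) and *Ttr* (12.21, -1.29), and 1 of the 25 members, *Sox17*, is also in the endothelial list. Such a correlation is what carried tissue would give, but a regulated programme of the same cells would give it too, and diet stays open as a cause. With the Y-linked mean as a covariate, as a stand-in for fetal sex, the list mean difference was -0.72 with a 95% interval of -1.82 to 0.38, which was the test first used and did not settle it. The Y-linked mean itself differed by only 0.28 between the diets, with 1 low array in each. The part of the list difference that it carried was therefore bound to be small, 0.025 with a 95% interval of -0.042 to 0.092. This balance leaves the stand-in little room as a source, but the sex of the pooled fetuses is not known. Leaving out both arrays with low Y-linked signal, 1 of each diet, gave a difference of -1.13.

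Of the 35 ways to split the 8 arrays into 4 and 4, 2 gave at least as many genes as the real split, which gave 1, and the highest of the others gave 2, so chance cannot be excluded for the count of genes. The other split set control dams 1 to 3 and iron-deficient dam 2 against the rest, and its genes were *Ttr* (adjusted p 0.005745) and *Apoa2* (0.03359), which encode plasma proteins made by yolk sac endoderm, so that split follows the yolk sac list mean. For the lists, 27 of the 35 splits gave at least as many as the real 2, and the highest of the others gave 12, which points to a structure of the samples that the preset correlation does not cover. Chance cannot be excluded for the list calls.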

How the results depend on the processing

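The yolk sac covariate and the setting without both arrays of low Y-linked signal were chosen after the data were seen. Over the alternatives, 139 named genes had 2859 values, of which 2827 kept their direction and their side of the threshold, 13 (all of *Alox15*) lost the call and 19 in 5 genes changed sign. The 29 lists had 689 values, of which 618 kept both, 8 lost a call, 21 gained one (endothelial 7, integrated stress response 6, giant cell 3, interferon response 2, nutrient transport 2 and macrophage 1, each with the preset correlation) and 42 in 16 lists changed sign, always around a difference that had not passed. A covariate's own list and genes were left out, and a list's direction was taken from its mean difference, a choice made after the values were seen. The causes were not tested. The number higher, 1 in the main comparison, was 0 with the replicate block, with the dimmest 25% of genes left out (where the adjusted p of *Alox15* was 0.05414), with trend and robust variance, with the erythroid or the yolk sac mean as covariate, without both arrays of low Y-linked signal and over all features. It was 113 (146 lower) at an unadjusted p with a 1.5-fold difference and 11 (9 lower) with a 2-fold difference, and 0 to 1 with each dam left out. The number of lists, 2 in the main comparison, was 4 after another quantile normalization, with the dimmest 25% left out and with array weights, 5 without both arrays of low Y-linked signal, 1 with the yolk sac mean as covariate, 0 with an estimated correlation and by fry, and 1 to 7 with each dam left out (7 without control dam 3, 4 without iron-deficient dam 4, and 1 without control dam 2, iron-deficient dam 2 or iron-deficient dam 3). The first principal component of the 1000 most variable genes held 26.2167% of the variance. The dam numbers pair no animals, and the residuals of dams with the same number correlated at -0.003, -0.12, -0.023 and 0.008. With the replicate number as a block 0 genes passed, and *Alox15* had the same difference of 4.39 with an adjusted p of 0.3908.

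Values that changed sign were, after quantile normalization, heme synthesis at 0.0179. With the dimmest 25% of genes left out it was erythroid at -0.0245, and with the dimmest 50% left out heme synthesis at 0.0012, erythroid at -0.1104, labyrinth at 0.0035 and inflammation at 0.0863. With array weights these were *Ddx3y* at -0.0935 and *Fth1* at 0.0091, and with the decidual mean as covariate -0.1722 and 0.0121. With the yolk sac mean as covariate they were *Fth1* at 0.0321, *Alas2* at 0.123, heme synthesis at 0.024, oxidative phosphorylation at -0.0613, decidual stroma at 0.0051, Nrf2 targets at 0.0254, inflammation at 0.0185 and immediate early genes at 0.0299. Without both arrays of low Y-linked signal they were *Ddx3y* at -0.1133, hypoxia targets at -0.0238, erythroid at -0.1717, cathepsins at 0.0265 and neutrophil at -0.0163. With each dam left out, ranges that crossed 0 were heme synthesis -0.0583 to 0.0352, iron-sulfur assembly -9e-04 to 0.0547, oxidative phosphorylation -0.0476 to 0.0769, hypoxia targets -0.0126 to 0.0517, *Alas2* -0.4792 to 0.1142, labyrinth -0.072 to 0.044, *Fth1* -0.1108 to 0.0725, erythroid -0.134 to 0.116, prolactin family -0.1956 to 0.037, cathepsins -0.0633 to 0.0429, decidual stroma -0.1254 to 0.0829, Nrf2 targets -0.0703 to 0.0383, inflammation -0.1658 to 0.0229, *Eif2s3y* -0.7117 to 1.6383, *Ddx3y* -1.4075 to 1.3342, *Hmox1* -0.3508 to 0.0358, junctional zone -0.0073 to 0.1367, cholesterol synthesis -0.0235 to 0.1002 and imprinted -0.0711 to 0.004. Without changing sign, these came below 50% of their main value with a dam left out, at the value nearest 0: neutrophil 0.0019, proliferation -0.0045, steroid synthesis 0.0333, nutrient transport -0.0473, immediate early genes -0.0058, *Fech* -0.0817, *Ndufa5* -0.1317, *Ascl2* 0.1325, *Ctsj* 0.2008, *Esr1* -0.2325, *Pgr* -0.255, *Ramp3* 0.1758, *Igfbp3* 0.1533, *Cd247* 0.1408, *Hsd17b3* 0.1133, *Cxcl2* -0.1692, *Slc40a1* -0.0658 and *Ftl1* 0.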

Other observations

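The test of red cell content, the tests of the globins and the limit on the brightness of markers were chosen after the results were seen. Among features without a gene name, those with the smallest p did not pass the test. Feature TC1900000984.rn.2 was 10.93 ± 0.20 in control and 11.94 ± 0.24 in iron-deficient placentas (limma adjusted p 0.3256) and feature TC0800003433.rn.2 was 5.15 ± 1.01 and 7.79 ± 0.85 (0.3786).

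For *Alox15*, 3 changes in cell content were weighed. More red cells or precursors cannot be told apart from other sources. The 31 erythroid genes had a median difference of -0.0975, but the globins among them start from high levels that would hide a small share of immature cells. *Hbz* (2.46), *Gfi1b* (1.01), *Hbe1* (0.93) and *Trim10* (0.90) were higher and passed when adjusted over the list alone. On the other side, 19 of the 31 were lower. At an unadjusted limma p below 0.05, 6 members were higher and 5 lower. The 9 measured eosinophil markers had a median of 0.0625, with *Ccr3* highest at 0.57 and the granule gene *Prg2* at -0.02. This met the bound set beforehand against eosinophils, but that bound was wrong in asking nothing of brightness. All 9 were dimmer than the median gene, between the 6.1 and the 37.9 brightness percentile. By the limit on brightness chosen afterwards, eosinophils therefore cannot be told apart either. The 12 measured markers of alternatively activated macrophages, cells that can express *Alox15*, had a median of -0.105, with *Arg1* at -0.13 and *Mrc1* at -0.42, and 2 of them are also in the macrophage list. Of these, 8 were dimmer than the median gene and exclude nothing. The 4 brighter ones, *Mrc1*, *Clec10a* (-0.27), *Tgm2* (-0.08) and *Il4r* (0.16), had a median of -0.1725. Among them *Tgm2*, at a control mean of 16.425, starts from a level that would also hide a small share of cells. So few markers show no rise of these cells but cannot exclude it. Immature red cells, eosinophils, alternatively activated macrophages, a change within a cell type and the diet as a cause stay open.

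The globin shift may reflect more embryonic globin in fetal red cells of the placenta, while less adult globin is not shown, since the adult mean differed by -0.47 with an exact permutation p of 0.1714 and the diets overlapped. A different amount of blood, with the same mix of maternal and fetal blood, would move both groups the same way. A change in that mix could move them apart and was not tested. The shift of 1.59 between embryonic and adult globins restates the pattern. The adult mean, with a 95% interval of -1.15 to 0.21, did not follow the embryonic mean (1.12). *Hbe1*, at a control mean of 17.30 as bright as the adult globins, was nevertheless higher by 0.93. For these globins, grouped after their values were seen, this weighs against the amount of blood, at an unchanged mix, as the whole source without excluding it. *Hba-a1*, near the top of the scale at a control mean of 19.37, could hardly show a rise, but the other adult globins were lower. The Y-linked mean, a stand-in for fetal sex, differed by only 0.28 between the diets, with 1 low array in each. As a covariate it could therefore remove little of the shift, which stayed at 1.63 with a 95% interval of 0.99 to 2.27. This balance leaves the stand-in little room as a source, but the sex of the pooled fetuses is not known. Carried yolk sac tissue, where embryonic red cells form early in gestation, would raise the yolk sac genes along with any embryonic globins it brought. Whether it brings them on day 18.5 was not tested. The yolk sac list mean was lower, without passing (-0.69, 95% interval -1.73 to 0.34, exact permutation p 0.1714). The embryonic globin mean shifted by 1.82 against that list mean, with a 95% interval of 0.56 to 3.07. That value combines 2 differences already seen and is no independent test. The arrays thus gave no sign of more carried tissue, which weighs against this source without excluding it. The test first used, with the yolk sac mean as covariate, gave a shift of embryonic against adult globins of 1.63 with an interval of 0.48 to 2.78, which reached just below the bound of 0.5 and did not settle it. The iron-deficient dams with the higher *Alox15* values were dams 1 and 2, at 11.36 and 11.91 against 9.63 and 9.36. They also had the higher embryonic minus adult difference, -4.02 and -3.93 against -4.84 and -5.14. The erythroid gene *Gfi1b* ran the other way, at 6.11 and 5.77 against 6.81 and 7.09. *Trim10* lay between 5.22 and 5.31 on all 4, and 4 dams are too few to test these relations.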
